A study of Mus musculus with 6 samples.

How the data were processed

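Total RNA of whole mammary glands from virgin female FVB mice was depleted of ribosomal RNA, made into directional libraries with a kit that marks the strand and sequenced as single-end reads on a NextSeq500, per the labels' protocols. The deposited table gives counts of reads per gene, not normalized, for all 6 libraries. The submitters' processing notes name bcl2fastq, Trimmomatic, STAR 2.6.0c, featureCounts, DESeq2 and the genome build GRCm38, without saying which settings were used. The strand setting of the counting, the treatment of reads that map to several places and the annotation are not given in the sources used here. All 55450 gene identifiers in the table, versions included, matched GENCODE release M21 on GRCm38, from which symbols, coordinates and overlaps were taken. Because the strand setting is unknown, genes that overlap another gene are treated as uncertain.

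Libraries were grouped by the genotype in their titles into 3 WT and 3 Hpn-/- samples. The labels number the samples within each genotype, and the p-values measure the spread between these samples. Each title carries its own identifier, and each library was counted as a separate sample. No pair of libraries within a group agreed within sampling noise (chi-square per degree of freedom of 6.72 to 32.1 over the tested genes). Repeat preparations of the same animal could also differ by more than sampling noise, so these values do not show separate animals.

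Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, with its minimum count of 10 and minimum total of 15, which left 12520 genes. Library sizes were scaled by TMM, with factors from 0.914 to 1.24, and a quasi-likelihood model with robust estimation was fitted with genotype as its only term. Two-sided p-values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 was called. The common biological coefficient of variation was 0.154 and the median standard error of a log2 fold change was 0.192. A log2 fold change is Hpn-/- minus WT throughout, and values per library are CPM scaled by TMM.

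Before the data were examined, 34 gene lists were fixed for TGF-beta signalling, extracellular matrix, hepsin and its substrates, the neighbours of Hpn, mammary epithelium, fat, metabolism, other cell types of a gland, the cell cycle, interferon, immediate early genes, Wnt and early growth. The 31 lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and adjusted over these lists. Camera with an estimated correlation and fry were run beside it, and neither called a list in one direction. With an estimated correlation camera uses only the residual degrees of freedom of the 6 libraries, so it could hardly call a list here. Fry's test of change in either direction is given where it passed. A list score is the mean over its members of log2 CPM centred on each gene's mean. Lists share members in places, such as Col5a1 and Timp1.

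The genes named in the text follow a rule fixed before the data were examined. It takes Hpn, up to 10 called genes per direction whose groups did not overlap, and, where fewer were called, the 5 genes of smallest p that did not pass, as well as, of each list, the 3 members of smallest p and the most abundant one, with up to 3 more for called lists and the TGF-beta lists. Predicted genes were counted but not named. Gm42418 and the libraries left out were chosen for mention after their values were seen.

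The test was checked on simulated counts for the 12520 genes of this comparison with the means, library sizes and dispersions of the 6 libraries and 200 changed genes. With dispersions from the fitted trend it recovered 20% of the genes changed 1.5-fold, 74% at 2-fold, 98% at 3-fold and 96% at 4-fold, and 6 of its 150 calls were wrong. With a dispersion per gene the shares were 10%, 66%, 92% and 100%, and 7 of 141 calls were wrong. A simulated list of 25 genes shifted 1.4-fold was called, and 0 of 30 unshifted lists were. Genes were simulated independently of each other, so this does not show how often the list test makes false calls among correlated genes such as those of the real lists.

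The alternatives fixed before the data were examined were RLE and upper quartile scaling, no count filter, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom with and without sample weights, preranked fgsea 1.28.0 for the lists, the replicate number as a block, age as a covariate with and without the 2 week library, a 2-fold minimum and leaving out each library in turn. Leaving out the loci derived from ribosomal RNA and using a muscle score or a lymphocyte score as a covariate were added after seeing the data, as were 5 further gene lists used in the closing observations. Except for the mean of Errfi1 and Sik1, whose 95% interval is computed from their standard errors, intervals over genes come from 10000 bootstrap draws of the members at 95%, and they treat the members as independent, which they are not. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.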

Results

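Whole mammary glands of virgin female FVB mice were profiled by total RNA sequencing after removal of ribosomal RNA. The series holds 6 libraries, 3 from wild-type (WT) mice and 3 from Hpn-/- mice, in which the hepsin gene had been disrupted with CRISPR/Cas9. Hepsin, the product of Hpn, is a transmembrane serine protease of epithelial cells. The mice differed in age. WT replicate 1 was 2 weeks old, WT replicate 2 was 6 weeks old and WT replicate 3 was 5 weeks old, whereas Hpn-/- replicates 1 and 2 were 6 weeks old and Hpn-/- replicate 3 was 5 weeks old. The deposited gene counts summed to 14207461, 10971661 and 11850272 in WT replicates 1, 2 and 3, and to 12218216, 11829392 and 18807615 in Hpn-/- replicates 1, 2 and 3. The predicted gene Gm42418, which overlaps a ribosomal RNA repeat, took 54.0% to 61.5% of these counts, and all loci derived from ribosomal RNA together took 78.0% to 84.3%. Between 1798932 and 3071401 counts per library were left for all other genes, which limits the precision for genes of low abundance.

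The targeted gene was examined first, as a check of the genotype labels. Hpn (ENSMUSG00000001249.14, chromosome 7, 31098725 to 31115290, minus strand, GRCm38) had 12, 6 and 4 counts in WT replicates 1, 2 and 3, and 4, 3 and 5 counts in Hpn-/- replicates 1, 2 and 3. Its level was 0.588 ± 0.260 CPM (counts scaled to a common library size) in WT and 0.277 ± 0.0136 CPM in Hpn-/- glands (SD, n = 3 each). The 22 WT counts against 12 Hpn-/- counts gave a ratio of 0.460, with an exact 95% interval of 0.207 to 0.971 that covers counting error only. WT replicate 3 (0.336 CPM) lay close to the Hpn-/- libraries (0.264 to 0.291 CPM). Hpn lay under the count filter and was therefore not among the tested genes. In an edgeR fit without that filter its log2 fold change was -1.07 (SE 0.589, adjusted p = 0.810), and without the 2 week WT replicate 1 it was -0.66. A decrease was thus not called at this depth, and counts of the gene remained in all 3 Hpn-/- libraries. Where in the gene the disruption lies is not given in the sources used here, and a transcript can persist after a frameshift.

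The comparison of Hpn-/- with WT glands asks which transcripts depend on hepsin in the virgin gland. Errfi1 and Sik1 were the genes that passed the test. Errfi1 (ENSMUSG00000028967.10, chromosome 4, 150853919 to 150868892), an inhibitor of the EGF receptor, rose from 7.51 ± 1.17 CPM in WT to 17.8 ± 3.54 CPM in Hpn-/- glands (SD, n = 3 each), a log2 fold change of 1.24 (SE 0.171, adjusted p = 0.0212). Sik1 (ENSMUSG00000024042.7, chromosome 17, 31844250 to 31855804), a salt-inducible kinase, rose from 12.0 ± 1.45 to 24.2 ± 4.08 CPM, a log2 fold change of 1.01 (SE 0.150, adjusted p = 0.0231). All 3 Hpn-/- libraries lay above all 3 WT libraries for both genes. No gene fell past the threshold.

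The count of 2 higher and 0 lower genes came from edgeR's quasi-likelihood test over 12520 genes. At an unadjusted p under 0.05 the same test had 498 higher and 363 lower genes (861 in all), against 626 in all that chance gives on average. Other splits of the 6 libraries, 3 against 3, gave from 189 to 1787 such genes, and those with 954 and 1787 exceeded the genotype split. DESeq2 called 8 higher and 0 lower genes, with 286 higher and 215 lower at the unadjusted threshold. Limma-voom called 2 higher and 0 lower genes, with 457 and 387 at the unadjusted threshold. The groups did not overlap for 744 genes that were higher and 631 that were lower in Hpn-/- glands, and chance alone gives 626 in each direction. The count depended on single libraries. No gene was called without WT replicate 1, without WT replicate 2 or without Hpn-/- replicate 2, 1 higher gene was called without Hpn-/- replicate 1 and 4 without WT replicate 3. Without the 5 week Hpn-/- replicate 3, 89 genes were higher and 111 lower. Only Hpn-/- libraries of 6 weeks remained in that fit, against WT libraries of 2, 5 and 6 weeks. Wherever that library is left out, genotype is therefore partly confounded with age. Errfi1 lost its call without WT replicate 1 (log2 fold change 1.14, adjusted p = 0.112), WT replicate 2 (1.21, adjusted p = 0.110) or Hpn-/- replicate 2 (1.13, adjusted p = 0.223). Sik1 lost its call without any single library except Hpn-/- replicate 3, at log2 fold changes of 0.88 to 1.09 and adjusted p of 0.0541 to 0.255. With the libraries of 5 and 6 weeks alone and age as a covariate, Errfi1 was at 1.18 (adjusted p = 0.0337) and Sik1 at 0.87 (adjusted p = 0.0537). With age as a covariate in all 6 libraries neither was called (adjusted p = 0.248 and 0.336).

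The genes next in rank did not pass in edgeR with all 6 libraries and the count filter. On the higher side they were Ccn2, a matricellular growth factor, at a log2 fold change of 1.93 (0.629 ± 0.188 against 2.46 ± 0.527 CPM, SE 0.331, adjusted p = 0.0896), and Ddit4, an inhibitor of mTORC1, at 1.36 (4.82 ± 1.80 against 12.5 ± 2.40 CPM, adjusted p = 0.157). Snora73b, Irs2 and Nlrc3 followed with 0.76, 0.70 and 0.76 and adjusted p of 0.264, 0.264 and 0.270. On the lower side the proteoglycan Vcan had a log2 fold change of -0.71 (23.2 ± 2.36 against 14.1 ± 2.96 CPM, adjusted p = 0.300). Plau, the urokinase plasminogen activator whose proenzyme is a known substrate of hepsin, was at -0.63 (13.0 ± 1.36 against 8.42 ± 0.377 CPM, adjusted p = 0.313). Cbr2, Cdh2 and Egfr were at -0.75, -0.85 and -0.69, each with an adjusted p of 0.367. Ddit4 passed with DESeq2 (adjusted p = 0.00161) and without WT replicate 3 (1.71, adjusted p = 0.00462). With no count filter each of these 10 genes except Cdh2 passed (Cdh2 adjusted p = 0.0723). The median prior degrees of freedom were infinite in that fit, so for most genes a common trend replaced the gene's own spread. With the muscle score as a covariate, an alternative chosen after seeing the data, Ccn2, Ddit4, Snora73b and Irs2 passed (adjusted p of 0.0135 to 0.0447), and without Hpn-/- replicate 3 each of these 10 genes except Plau passed (Plau adjusted p = 0.0546). In each of these 10 genes the libraries of the groups did not overlap. Snora73b lies within Rcc1 and Snhg3 on the same strand, and Ccn2, Irs2, Vcan and Egfr overlap an annotated gene on the opposite strand, so their counts are uncertain.

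**Figure D1:**
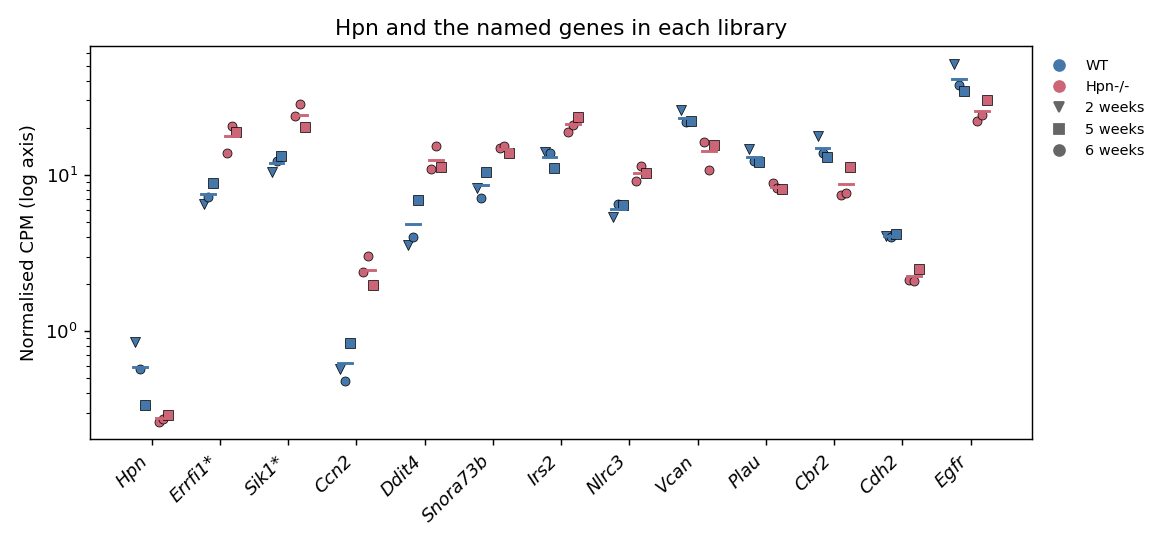
Normalised CPM on a log axis of Hpn and the named genes in each of the 6 libraries. Points are libraries, with colour for the genotype and shape for the age in weeks, short lines are group means (n = 3), and an asterisk marks Errfi1 and Sik1, which passed the test; Hpn in WT replicate 3 (0.336 CPM) sits next to the Hpn-/- libraries (0.264 to 0.291 CPM).

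Lymphocyte transcripts were higher in the Hpn-/- glands. All 20 tested members of the T and NK cell list had values above those of WT, with a median log2 fold change of 0.45, and 18 of 19 members of the B cell list, with a median of 0.45. Among the T cell genes, Cd8b1 was at 3.08 ± 0.728 CPM in WT and 5.01 ± 0.313 CPM in Hpn-/- glands (log2 fold change 0.71) and the interleukin-7 receptor gene Il7r at 1.13. Among the B cell genes, Bank1 was at 0.53, the complement receptor Cr2 at 0.60 and Cd74, the most abundant member, at 0.45 (74.9 ± 6.19 against 102 ± 18.1 CPM). No member passed over all genes tested, whereas 11 T and NK cell genes and 6 B cell genes passed when adjusted over the list alone. Camera called both lists (adjusted p = 2.79e-12 and 2.18e-09), and the calls were lost with an estimated correlation (adjusted p = 0.600 for each). The list scores of all 3 Hpn-/- libraries lay above those of all 3 WT libraries, for which an exact two-sided permutation test gives p = 0.1, the smallest it can give with 3 against 3. Without the 2 week library the medians were 0.41 and 0.46, and with age as a covariate among the 5 and 6 week libraries they were 0.35 and 0.40. Without Hpn-/- replicate 2 they were 0.31 and 0.29, and without Hpn-/- replicate 3 they were 0.54 and 0.52, with 2 members of each list passing over all genes.

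Inducible genes of the immediate early and stress list were also higher. Of its 22 tested members 19 had higher values, with a median log2 fold change of 0.24. Nr4a1, an orphan nuclear receptor, was at 1.23 (2.62 ± 0.986 against 5.98 ± 1.63 CPM) and the phosphatase gene Dusp1 at 1.29 (5.19 ± 2.22 against 12.5 ± 1.38 CPM), and these 2 passed when adjusted over the list alone, while none passed over all genes. Btg2 and Klf6 were at 0.47 and 0.38, and Jund, the most abundant member, at 0.04. Camera called the list (adjusted p = 0.000783), but not with an estimated correlation (adjusted p = 0.600). The call was also lost without Hpn-/- replicate 3 (adjusted p = 0.0797). The list score was higher in all 3 Hpn-/- than in all 3 WT libraries (exact two-sided permutation p = 0.1). In fry's test of change in either direction the list was called (adjusted p = 0.0194).

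Collagen and proliferation genes were lower in the Hpn-/- glands as sets. Of 29 tested genes for fibrillar collagens and their crosslinking, 27 had lower values, with a median log2 fold change of -0.36. Col3a1, its most abundant member, was at 1409 ± 234 CPM in WT and 997 ± 228 CPM in Hpn-/- glands (log2 fold change -0.50). Col5a1 was at -0.55, Col1a2 at -0.53 and the crosslinking enzyme Loxl2 at -0.43. All 24 tested cell cycle genes had lower values, with a median of -0.50. Mki67, a marker of proliferating cells, was at 16.7 ± 4.68 against 10.4 ± 2.33 CPM (log2 fold change -0.67), and Cdk1 at -1.18. No member of either list passed over all genes or adjusted over the list alone. Camera called both lists (adjusted p = 2.10e-10 and 1.58e-08), and neither call held with an estimated correlation (adjusted p = 0.600 for each). Neither held with the lymphocyte score as a covariate (adjusted p = 0.685 and 0.229), which separates the genotypes and so takes up much of the genotype term. Without Hpn-/- replicate 3 the medians were -0.57 and -0.68, and 11 collagen and 2 cell cycle members passed over all genes. Without the 2 week WT replicate 1 the medians were -0.25 and -0.47, and no member passed.

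Neither score separated the genotypes, since the 5 week Hpn-/- library lay above the 6 week WT library in both (exact two-sided permutation p = 0.2 for each). Among the 6 week libraries the collagen score, the mean centred log2 CPM of the members, was -0.0173 in WT replicate 2 and -0.333 and -0.410 in Hpn-/- replicates 1 and 2. In the 5 week libraries it was 0.199 in WT replicate 3 and 0.113 in Hpn-/- replicate 3. The 2 week WT replicate 1 had the highest score, 0.449. The cell cycle score was -0.164 against -0.539 and -0.257 at 6 weeks and 0.516 against 0.107 at 5 weeks. With age as a covariate among the 5 and 6 week libraries the median log2 fold changes were -0.21 for collagens and -0.38 for the cell cycle, and camera with the preset correlation called both (adjusted p = 2.70e-05 and 2.91e-05).

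**Figure D2:**
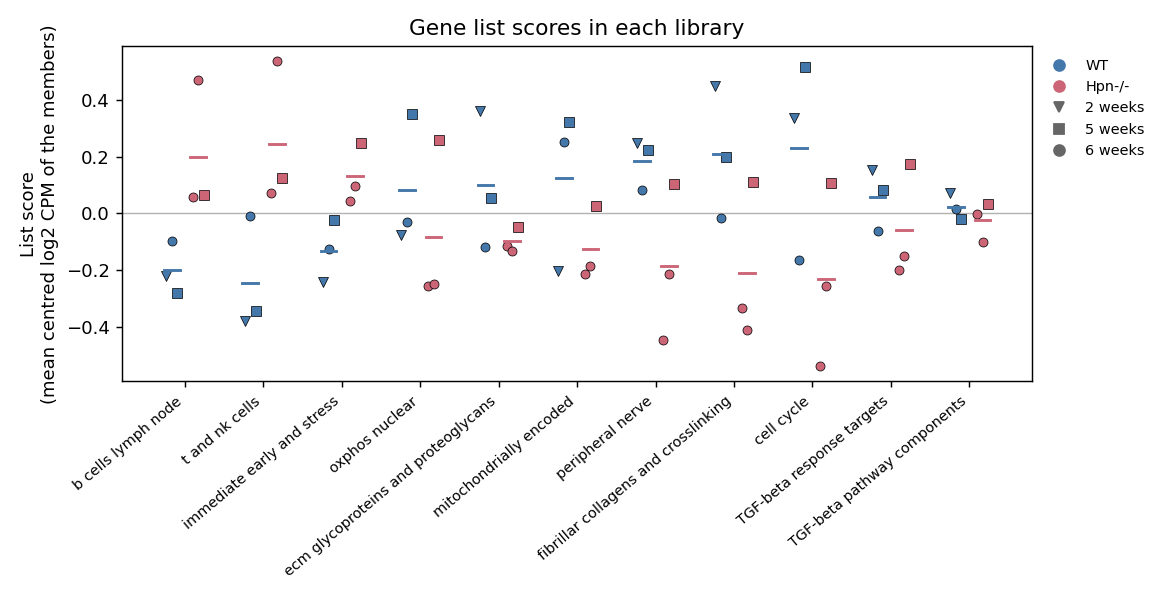
Score of each called gene list and of the TGF-beta lists in the 6 libraries, as the mean log2 CPM of the members after centring each gene on its mean. Points are libraries, with colour for the genotype and shape for the age in weeks, and short lines are group means (n = 3). The lymphocyte and immediate early lists separate the genotypes. In the collagen, cell cycle, oxidative phosphorylation and mitochondrially encoded lists the 5 week Hpn-/- library lies nearer to the 5 week WT library than the 6 week Hpn-/- libraries do.

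The called lists that remain were lower in Hpn-/- glands. The nuclear genes of oxidative phosphorylation had 25 of 30 lower values (median log2 fold change -0.18, adjusted p = 0.00564), and all 9 tested mitochondrially encoded genes had lower values (median -0.25, adjusted p = 0.00573). The mitochondrially encoded list includes the ribosomal RNA genes mt-Rnr1 and mt-Rnr2, the latter its most abundant member. With the loci derived from ribosomal RNA left out, its camera adjusted p was 0.0256. Matrix glycoproteins and proteoglycans had 19 of 29 lower values (median -0.24, adjusted p = 0.00573), with Fbn1 at -0.45, Efemp2 at -0.50 and Fmod, against the direction of the list, at 0.75. Fn1, which encodes fibronectin and was the most abundant of them, did not differ by more than the spread between libraries (455 ± 107 against 433 ± 75.7 CPM, log2 fold change -0.07, SE 0.196). Vcan passed when adjusted over this list alone (adjusted p = 0.00784). Peripheral nerve genes had 10 of 13 lower values (median -0.30, adjusted p = 0.0223). No member of these 4 lists passed over all genes, and no member of the other 3 passed adjusted over the list alone. With an estimated correlation the adjusted p was 0.600 for the nerve list and 0.726 for the others. Over all 9 called lists the estimated correlation between members ran from 0.0347 for the immediate early list to 0.846 for nuclear oxidative phosphorylation, against the preset 0.01. Correlation need not be the only reason for the lost calls. The uncalled estrogen and progesterone targets, with an estimated correlation of 0.00507, also went from a camera adjusted p of 0.0868 to 0.600. That test uses only the residual degrees of freedom of the 6 libraries, so a lost call does not decide whether a list differs.

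These 4 calls were lost when single libraries were left out. The matrix glycoprotein call was lost without the 2 week WT replicate 1 (median -0.06, adjusted p = 0.717), and the nerve call without that library (adjusted p = 0.0932) or without Hpn-/- replicate 1 (adjusted p = 0.401). On all 6 libraries the nerve call was also lost with fgsea (adjusted p = 0.0699) and with no count filter (adjusted p = 0.0654). The oxidative phosphorylation call was lost without WT replicate 3 (median -0.02, adjusted p = 0.622), Hpn-/- replicate 1 (-0.09, adjusted p = 0.289) or Hpn-/- replicate 2 (-0.09, adjusted p = 0.222), and the mitochondrially encoded call without WT replicate 2 (-0.19, adjusted p = 0.0648), WT replicate 3 (-0.16, adjusted p = 0.115) or Hpn-/- replicate 1 (-0.22, adjusted p = 0.0619). In the other direction, the oxidative phosphorylation median was -0.36 without Hpn-/- replicate 3 (30 of 30 lower, adjusted p = 2.01e-07) and -0.28 without WT replicate 1 (adjusted p = 4.37e-05), and the mitochondrially encoded median was -0.36 without either. With age as a covariate in all 6 libraries the matrix glycoprotein and nerve lists were not called (adjusted p = 0.764 and 0.156).

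The TGF-beta lists were not called. Of 26 tested TGF-beta response genes 15 had lower and 11 higher values (median log2 fold change -0.07, adjusted p = 0.153), and the members went both ways. At an unadjusted p under 0.05, 9 were lower and 3 higher, against 363 lower and 498 higher of all 12520 tested genes. Col3a1, the most abundant member, was at -0.50 and Col5a1 at -0.55, and both are also in the collagen list. Ccn2 was at 1.93 and passed when adjusted over the list alone (adjusted p = 0.000558), and Tgfbi was at 0.45. Id1 was at -0.57, Timp1 at -1.34 and Snai2 at -0.72. Without Hpn-/- replicate 3 the list was called lower (median -0.24, adjusted p = 0.00694), as it was with preranked fgsea (adjusted p = 0.0235) and with limma-voom and sample weights (adjusted p = 0.0485). Camera with an estimated correlation gave an adjusted p of 0.726. Of 24 components of the pathway 14 had lower and 10 higher values (median -0.03, adjusted p = 0.510), and none passed in either adjustment. Ltbp1 was at 0.37, Smad7 at 0.29, Tgfbr3 at -0.23, Acvrl1 at -0.24 and Tgfbr2, the most abundant, at -0.11.

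Lists close to hepsin itself were not called either. Of 9 tested proteases and inhibitors related to hepsin 5 had higher and 4 lower values (median log2 fold change 0.30, adjusted p = 0.472). Fry's test of change in either direction called this list (adjusted p = 0.000476). Its median was 0.08 without WT replicate 1 and 0.02 with age as a covariate among the 5 and 6 week libraries, each over 10 tested members. With age as a covariate in all 6 libraries, over 9 members, it was 0.32. The direction of the list turned to lower without Hpn-/- replicate 2 (adjusted p = 0.898). Without Hpn-/- replicate 3, 1 member other than Plau (edgeR adjusted p = 0.0546) passed over all genes. Plau passed when adjusted over this list alone (adjusted p = 0.00315), Serpine2 was at -0.64 and the urokinase receptor gene Plaur at 0.83. The largest log2 fold change in the list, 1.57, was in a member that the naming rule does not take. The list for hepatocyte growth factor signalling had a median log2 fold change of -0.01 but a mean of 0.02 and a camera direction of higher (adjusted p = 0.905), with Met at 0.09 and Spint2 at 0.30. Metalloproteases had a median of 0.03 but a mean of -0.09 and a camera direction of lower (adjusted p = 0.371), with Adamts2 at -0.47, and fgsea called them lower (adjusted p = 0.0461). The 8 tested neighbours of Hpn on chromosome 7 had a median of -0.09 (adjusted p = 0.470). The basement membrane list had a median of -0.12 (adjusted p = 0.0868), with Lamc1 at -0.32, and was called lower without WT replicate 2 (adjusted p = 0.0171), with limma-voom (adjusted p = 0.0309) and with sample weights (adjusted p = 0.0318). Camera with an estimated correlation gave an adjusted p of 0.726 for both the basement membrane and the metalloprotease lists.

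Mammary epithelial and hormone lists were not called by camera with the preset correlation in all 6 libraries. Luminal genes had 18 of 23 higher values (median log2 fold change 0.25, adjusted p = 0.0868), although Areg, the EGF receptor ligand amphiregulin, was at -0.92 (3.72 ± 0.328 against 1.91 ± 1.14 CPM) and the keratin Krt8 at -0.49. Basal and myoepithelial genes had a median of 0.05 (adjusted p = 0.559), with Myh11 at 0.07, and camera gave the opposite direction. Milk genes had 11 of 12 higher values (median 0.30, adjusted p = 0.104), with Ltf at 0.46. Estrogen and progesterone targets had 8 of 11 lower values (median -0.16, adjusted p = 0.0868), with Prlr at 0.75 and Ccnd1 at -0.22. Without Hpn-/- replicate 3 the luminal and milk lists were called higher (adjusted p = 0.000194 and 0.00584), and the milk list also without WT replicate 2 (adjusted p = 0.0269). The direction of the milk list turned to lower without WT replicate 3 (adjusted p = 0.836), and without Hpn-/- replicate 1 its adjusted p was 0.857. Its score was lowest in the 5 week libraries of both genotypes, -1.07 in WT replicate 3 and -0.668 in Hpn-/- replicate 3. With limma-voom and sample weights the luminal and milk lists were called higher (adjusted p = 0.0463 and 0.0343) and the estrogen and progesterone targets lower (adjusted p = 0.0407), the last also with limma-voom alone (adjusted p = 0.0482), and fgsea called the milk list (adjusted p = 0.0486). With the muscle score as a covariate the luminal and milk lists were called higher (adjusted p = 0.0259 for each). With an estimated correlation the adjusted p was 0.726 for the luminal and milk lists and 0.600 for the hormone targets.

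Fat and lipid lists had medians of 0.09 for white adipocytes (adjusted p = 0.0868), 0.26 for lipogenesis (adjusted p = 0.0911) and 0.23 for cholesterol synthesis (adjusted p = 0.0868). Retn, which encodes the adipokine resistin, was at 0.73, Fasn at 0.27 and Pmvk at 0.44. On all 6 libraries these 3 lists were called higher with fgsea (adjusted p = 0.0361, 0.0342 and 0.0232), with limma-voom (adjusted p = 0.0325, 0.0482 and 0.0177) and with the lymphocyte score as a covariate, chosen after seeing the data (adjusted p = 0.00372, 1.36e-08 and 1.91e-05). They were also called higher without WT replicate 3 (adjusted p = 0.0072, 0.00303 and 0.0281) and without Hpn-/- replicate 2 (adjusted p = 0.0341, 3.00e-05 and 1.58e-05), and cholesterol synthesis also without WT replicate 2 (adjusted p = 0.0385). Without Hpn-/- replicate 1 the lipogenesis and cholesterol lists turned to lower (adjusted p = 0.593 and 0.739). That library had scores of 0.519 and 0.474 for them, against -0.238 and -0.239 in Hpn-/- replicate 2 and -0.0098 and 0.0095 in Hpn-/- replicate 3. In all 6 libraries the estimated correlations of the white adipocyte, lipogenesis and cholesterol lists were 0.106, 0.636 and 0.484, with adjusted p of 0.726, 0.769 and 0.726, so calls with the preset correlation are not firm. Brown adipocyte genes had 14 of 17 lower values (median -0.25, adjusted p = 0.228), with Ucp1 at -0.25. Without the 2 week WT replicate 1 that list was called lower (median -0.42, adjusted p = 2.25e-06), as it was without Hpn-/- replicate 3 (adjusted p = 0.0451) and with age as a covariate in all 6 libraries (median -0.32, adjusted p = 0.000169), with age among the 5 and 6 week libraries (adjusted p = 8.02e-06) and with the muscle score (adjusted p = 0.0404). Without WT replicate 3 its direction turned to higher (adjusted p = 0.566), and in all 6 libraries camera with an estimated correlation of 0.470 gave an adjusted p of 0.769.

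Markers of other cell types gave medians of -0.03 for macrophages (adjusted p = 0.472), -0.12 for endothelium (adjusted p = 0.0849) and -0.08 for fibroblasts (adjusted p = 0.371). Lyz2 was at 0.64 and passed when adjusted over the macrophage list alone (adjusted p = 0.0230), while Mrc1 was at -0.41. Sox18 was at -0.77 in the endothelial list and Pdgfra at -0.31 in the fibroblast list. Interferon response genes had a median of 0.16 (adjusted p = 0.371), with Usp18 at 0.71, and Wnt genes a median of 0.06 (adjusted p = 0.0868), with Sfrp2 at 1.30 and Lef1 at 0.55. Lef1 is also a member of the T and NK cell list. Genes of early postnatal growth had a median of -0.13 (adjusted p = 0.150), with Grb10 at -0.39, and its score was highest in the 2 week library (0.336 against -0.184 to 0.0772 in the others). Endothelial genes were called lower without WT replicate 2 (adjusted p = 0.0148) or Hpn-/- replicate 3 (adjusted p = 0.000523), Wnt genes higher without the same libraries (adjusted p = 0.0446 and 0.00848), and growth genes lower without WT replicate 3 (adjusted p = 0.0192). On all 6 libraries endothelial genes were called lower with fgsea, limma-voom, sample weights and the muscle score (adjusted p = 0.0361, 0.0356, 0.00857 and 0.0390), Wnt genes higher with fgsea and with no count filter (adjusted p = 0.0235 and 0.0247), growth genes lower with no count filter (adjusted p = 0.0372) and interferon genes lower with the lymphocyte score (adjusted p = 2.17e-06). With an estimated correlation the adjusted p was 0.769 for interferon genes and 0.726 for the other 3 of these lists. Too few members were tested for a set test of the erythroid, skin and granulocyte lists, in which Hbb-bs was at 0.07, Sbsn at 0.45 and Tpsb2 at -0.59.

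Skeletal muscle transcripts differed widely between libraries of both genotypes. They made up 0.888%, 0.190% and 0.0793% of the counts outside ribosomal RNA loci in WT replicates 1, 2 and 3, and 1.4%, 0.364% and 0.0223% in Hpn-/- replicates 1, 2 and 3, a 62.9-fold range. The list was not called (adjusted p = 0.570), and its median log2 fold change of 0.62 and camera's direction had opposite signs. It was called lower without WT replicate 3 (adjusted p = 0.0271) or Hpn-/- replicate 1 (adjusted p = 0.000131) and higher without Hpn-/- replicate 3 (adjusted p = 0.000118). In all 6 libraries its estimated correlation was 0.968, far above the preset 0.01, and camera with it gave an adjusted p of 0.922. Ttn was at 275 ± 285 CPM in WT and 445 ± 546 CPM in Hpn-/- glands. The first principal component, with 38.1% of the variance, placed Hpn-/- replicates 1 and 2 at 30.1 and 21.8, WT replicates 1 and 2 at -3.34 and -2.17, and WT replicate 3 and Hpn-/- replicate 3 at -24.6 and -21.7.

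Several of the list members named here overlap another annotated gene, and because the strand setting of the counting is unknown their counts are uncertain. They are Col1a2, Cd74, Lamc1, Ltbp1, Tgfbr3 and Mrc1, with a gene on the same strand, and Col5a1, Fbn1, Efemp2, Fn1, Dusp1, Jund, Timp1, Adamts2, Ccnd1, Usp18 and Sfrp2, with a gene on the opposite strand. Lef1 and Pdgfra overlap genes on both strands.

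**Figure D3:**
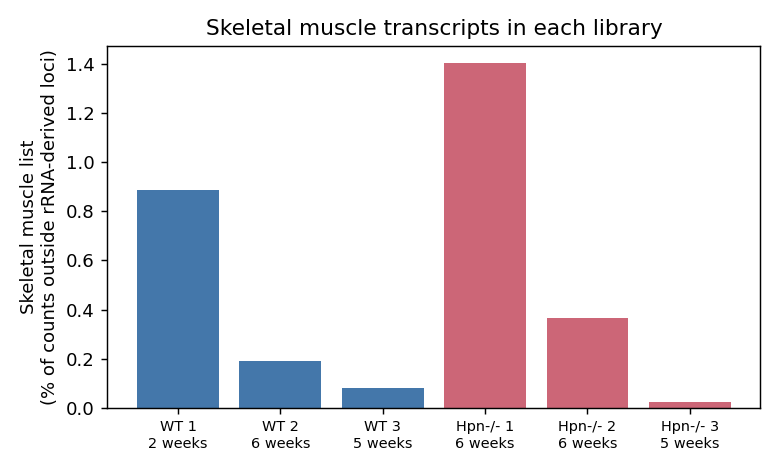
Share of the skeletal muscle gene list in the counts outside ribosomal RNA loci, in percent, for each of the 6 libraries. Bars are single libraries; the shares span 0.0223% to 1.4%, both in Hpn-/- glands.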

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

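The covariates for muscle and lymphocyte scores and the removal of ribosomal RNA loci were chosen after seeing the data. Hpn kept its direction without being called in all 18 alternatives that gave a value (log2 fold change -1.36 to -0.66, adjusted p from 0.677 to 1), and the 1 CPM filter gave none because Hpn lies below it. Errfi1 and Sik1 were higher in all 19 alternatives, past the threshold in 14 and 11 of them (log2 fold change 0.98 to 1.38 and 0.71 to 1.12). The counts of called genes with RLE, upper quartile, 1 CPM, limma-voom, 2-fold and ribosomal RNA settings stayed at 2 and 0.

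With no filter on low counts 76 genes were higher and 24 lower. The median prior degrees of freedom were infinite there, against 12.7 with the filter. DESeq2 called 8 higher genes. Age in weeks as a covariate left 0 higher genes, and the 5 and 6 week libraries with age had 3 higher genes and 1 lower gene. With the muscle score as a covariate 11 genes were higher and 3 lower, with the lymphocyte score 0 were higher. Without one library the higher genes ranged from 0 to 89 and the lower ones from 0 to 111. Higher lists numbered 8 with fgsea, 6 with limma-voom, 5 with sample weights, 5 with the muscle score, and 0 with an estimated correlation and with fry. Lower lists numbered 10 with sample weights, 1 with the lymphocyte score, and 0 with an estimated correlation and with fry. Without one library 3 to 6 lists were higher and 4 to 9 lower. The cause of these differences was not tested.

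The lymphocyte score separates the genotypes, so as a covariate it takes up much of the genotype term. It turned the medians of TGF-beta response genes to 0.0409, of TGF-beta components to 0.0230, of collagens to 0.0387, of matrix glycoproteins to 0.0343 and of oxidative phosphorylation to 0.108, none of them called.

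The titles share replicate numbers, and the sources used here do not say whether these pair the samples. The deviations of same-numbered libraries from their group means correlated at 0.167, 0.0732 and 0.368 across genes. Each Hpn-/- library correlated best with the WT library of its number, Hpn-/- replicate 2 only narrowly (0.0671 with WT replicate 1). WT replicate 2, however, correlated best with Hpn-/- replicate 1 (0.127). The common biological coefficient of variation was 0.120 with the block against 0.154 without it, so pairing stays open. With the replicate block 8 genes were higher, among them Il7r (1.09, adjusted p = 0.0177) and Ddit4 (1.37, adjusted p = 0.0342), and 1 lower. With it 6 lists were higher, among them the luminal, milk and Wnt lists (adjusted p = 0.0228, 0.00517 and 0.0241), and the endothelial list was lower (adjusted p = 0.0397).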

Other observations

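The tests of the 2 week library for the lymphocyte, collagen and cell cycle lists, and the gene lists added here, were chosen only after the results were seen. Among the added lists, 11 of 13 tested targets of cAMP and CREB signalling had higher values in Hpn-/- glands, with a median log2 fold change of 0.24 (camera adjusted p = 0.0352 over the 5 added lists, 0.409 with an estimated correlation). The phosphodiesterase genes Pde4b and Pde4d were at 0.57 and 0.42, while Areg was at -0.92. This list is not independent of the higher inducible genes, since it was added after Sik1, itself a CREB target, was seen to be higher, and Fos, Egr1 and Junb are also in the immediate early list. Lymph node stroma genes had 8 of 9 higher values (median 0.29, adjusted p = 0.0352, and 0.409 with an estimated correlation), with the chemokine genes Cxcl13 and Ccl21a at 0.43 and 0.42 and Lyve1 at -0.88. The other added lists were not called, with camera adjusted p of 0.253 for glucocorticoid targets (0.629 with an estimated correlation), 0.163 for evening clock genes and 0.978 for morning clock genes. No member of the 5 added lists passed over all genes. DESeq2, which called 8 genes, added Dusp1, Per1, Tsc22d3, Ddit4, Depp1 and Txnip to Errfi1 and Sik1, with log2 fold changes from 0.57 to 1.36. These genes are named after their values were seen.

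Lymphocyte transcripts were higher in the Hpn-/- glands, with a median log2 fold change of 0.45 over 39 genes. The age of the 2 week WT library as the whole cause is argued against, since the median without it was 0.41 (bootstrap 0.34 to 0.52). The muscle score had similar means in both genotypes (0.0636 ± 1.67 in WT and -0.0636 ± 2.74 in Hpn-/- glands, SD). As a covariate it could therefore hardly move the median, which was 0.45 (0.40 to 0.54), so muscle content was not tested by it. More lymph node tissue in the dissected Hpn-/- glands may contribute. Stroma markers outside the lymphocyte lists had a median of 0.21 (0.10 to 0.42, 7 genes, Glycam1 the most abundant at 42.1 CPM in WT and 51.6 CPM in Hpn-/- glands). Without Ltb, which lymphocytes also make, the interval was -0.39 to 0.43, with its lower end set by Lyve1. Glycam1, Lyve1 and Mfap4 also stand in the milk, macrophage and matrix glycoprotein lists, so too few markers of their own remain to decide, and dissection and genotype cannot be told apart here.

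Errfi1, Sik1 and other inducible genes were higher, and the mean log2 fold change of Errfi1 and Sik1 without the 2 week library was 1.03 (0.78 to 1.28 from the standard errors of both genes taken as independent, against 1.13 with it), which argues against that library as the whole cause. Higher glucocorticoid signalling may contribute. Its targets whose values had not been seen had a median of 0.10 (0.02 to 0.17, 18 genes, of which 1 had an unadjusted p under 0.05), above 0 as set beforehand for this cause but also far below the 1.24 of the leading genes, as set beforehand against it; since those genes were picked for their size, the bound against it was too strict and the question stays open. For a different phase of the circadian clock, evening genes minus morning genes gave -0.11, too small for the shift set beforehand, while Arntl at 0.39 lay outside the range set for no shift. Per1, Tsc22d3, Dusp1 and Ddit4, which DESeq2 called higher, were among neither the glucocorticoid targets nor the clock genes tested, so these medians leave them out. The time of dissection is not given in the sources used here.

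Collagen and cell cycle genes were lower, with a median of -0.41 over 53 genes. Without the 2 week WT library the median was -0.34 (-0.44 to -0.25), which argues against that library as the whole cause. With the muscle score as a covariate the median was -0.45 (-0.55 to -0.37), but that score had similar means in both genotypes and could hardly move it. With the lymphocyte score as a covariate camera called neither list (adjusted p = 0.685 for collagens and 0.229 for the cell cycle). That score separates the genotypes and takes up much of the genotype term. With age as a covariate among the 5 libraries of 5 and 6 weeks the medians were -0.21 for collagens and -0.38 for the cell cycle. That fit rests on 1 WT library of each age, so age from 5 to 6 weeks stays open for part of the difference.

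The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The genotype split called 2 genes, and the highest of the other splits called 7, so that 2 splits had as many. It called 9 lists, against 15 for the highest other split, and 7 splits had as many. That split sets the 3 libraries of 6 weeks against the younger ones and called 0 genes, with 1787 at an unadjusted p under 0.05 against 861 for the genotypes. The common biological coefficient of variation was 0.159 with age in weeks as a covariate in all 6 libraries against 0.154 without it, but 0.124 against 0.158 among the 5 and 6 week libraries, where age lowered it. On the first principal component the 2 week library lay beside the 6 week WT library, so these values do not settle whether the split reflects age. The split with 7 genes sets WT replicate 1 and Hpn-/- replicates 1 and 2 against the rest, and these are the 3 libraries with the largest share of muscle transcripts.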
